A study of Drosophila melanogaster with 4 samples.

How the data were processed

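Individual-nucleotide resolution crosslinking and immunoprecipitation (iCLIP) was performed in SL2 cells, a male Drosophila melanogaster cell line. RNA crosslinked to protein was recovered with a polyclonal rabbit antibody against Sister of Sex-lethal (Ssx) in 2 libraries and with control rabbit IgG in 2 libraries, per the labels. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

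The processing notes of the submitters name cutadapt 1.6, Bowtie 0.12.7, DESeq2 1.14.1 and DESeq, and the builds BDGP6 and dm6. The read counting, the handling of duplicate reads, the strand setting and the annotation are not given in the sources used here. The authors deposited 1 result table each for intervals in 5' UTRs, coding sequence (CDS), introns and 3' UTRs. Each row gives an interval, a gene name and the authors' statistics for the comparison of the 2 groups, and no column holds the values of a single library. Per the file headers, the mean value is the authors' signal per interval, a mean of normalized read counts over the libraries. The log2 fold change and its standard error were deposited by the authors on the log2 scale. The test statistic is a score that equals the fold change over its standard error in every deposited row, and the deposited p-value is the two-sided normal p of that statistic, both checked over all rows. Fold changes of the intervals with the lowest mean lay near 0, which is how moderated estimates look, so the folds of sparsely covered intervals are probably understated.

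The direction of the fold change is not written in the tables. A positive value was read as higher in the Ssx IP, which is likely because the tables were deposited as transcripts bound by Ssx and because the tool takes the alphabetically first group as the reference by default.

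The deposited adjusted p-values were used as they stand. In the 5' UTR table, 122 of 2159 intervals have one, 1023 of 8796 in the intron table, 289 of 4299 in the 3' UTR table, and in the CDS table all 1921. Intervals without an adjusted p have a mean under 3.54 in the 5' UTR table, under 5.65 in the intron table and under 7.36 in the 3' UTR table. The deposited adjusted p-values correspond to 183 intervals in the 5' UTR table and 550 in the 3' UTR table, more than the intervals listed with an adjusted p. The other intervals behind the adjustment were not analysed here. Intervals of different isoforms or of overlapping genes can hold the same reads, so counts are given for genes, and a gene was counted as enriched or depleted when any of its intervals passed an adjusted p of 0.05 with a positive or a negative fold change. A tested gene is one with at least 1 interval that has an adjusted p. No differential test was run on these tables, and values from them carry no SD or n.

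The analysis plan allowed for counts per library and, failing these, for counting and ranking the deposited statistics, which is what was done. Shares of genes have exact Clopper-Pearson 95% intervals. Two-sided Fisher's exact tests compared the overlap of regions, the X-linked share of enriched genes against chromosome arms 2L, 2R, 3L, 3R and 4, and the share of enriched members of 20 gene lists that were fixed before the data were examined. Lists were tested in a region with 3 or more tested members and at least 1 enriched gene. Zelen's exact test compared odds ratios between regions, and a Mantel-Haenszel odds ratio was computed within quintiles of the mean value. Benjamini-Hochberg adjustment was applied within each family of tests. Permutation tests drew 100000 resamples, and intervals of differences came from 10000 bootstrap draws over genes. Genes are not independent replicates, since all of them were measured in the same 4 libraries.

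The genes named in the text follow a rule set before the data were examined. For each region these are the 8 enriched genes with the largest fold change, the 4 with the smallest adjusted p, the 4 with the highest mean and the 3 depleted genes with the most negative fold change. Enriched members of the sex determination list, up to 4 enriched members of each other list, and Sxl, ssx, msl-2 and tra in every region that lists them were added. Of 4841 gene names, 4049 are current symbols and 4787 could be matched to a gene of the RefSeq annotation of Release 6, and 99.9% of the intervals of matched genes lie inside that gene.

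The normalized means rise in steps, because each is a sum of whole reads over 4 size factors. Within a relative tolerance of 1e-14 the steps gave a unique set of whole reads in 4 libraries for 100% of intervals in each table, at least 2 reads per interval. The solved libraries carry no names, so none was assigned to a sample or a group and no test used them. Their totals over non-overlapping listed intervals describe the depth. They were 3874, 3966, 696 and 352 reads in the 5' UTR table, 2201, 1314, 2983 and 651 in the CDS table, 70356, 58338, 15012 and 6038 in the intron table, and 16992, 17055, 4633 and 1752 in the 3' UTR table, each time in the order of decreasing size factor. These are reads in listed intervals and not the depth of the whole libraries. Only 28 CDS intervals and 43 5' UTR intervals had reads in all 4 libraries, against 1320 introns and 607 3' UTR intervals.

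The procedures were tested on simulated data. Of the reads simulated for the real intervals, 100% were solved exactly in the 5' UTR, CDS and 3' UTR tables and 7247 of 7249 intervals in the intron table, with 0 wrong solutions. With fold changes drawn around known values at the deposited standard errors, a log2 change of 3 was called in 30% of 20 changed 5' UTR intervals, 30% of 100 CDS intervals, 64% of 100 introns and 58.3% of 48 3' UTR intervals, and a log2 change of 6 in 75%, 88%, 100% and 97.9%. Of the unchanged intervals 1, 10, 5 and 0 were called in the 4 tables. Deposited folds of sparse intervals are moderated, so these rates hold for the assumed settings and do not show what the real intervals could reach. The X test on the 178 tested 3' UTR genes by Fisher's exact test passed the threshold in 3.3% of 1000 simulations with an odds ratio of 1 and in 100% with an odds ratio of 9.

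Alternatives included other thresholds for the adjusted p (0.01 and 0.1), a minimum fold of 2, a minimum mean of 10, an adjustment over the 4 regions together or over all listed intervals, other backgrounds, 1 interval per gene, overlapping genes counted once, overlaps of regions without genes whose enriched intervals overlap, and the opposite direction of the fold change for the X-linked shares. Alternatives that need counts per named library were not run. Uridine runs were to be counted in enriched intervals, and this was not done because no genome sequence was used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.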

Results

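To locate RNA contacted by Ssx, an RNA-binding protein and paralog of the sex determination factor Sex-lethal (Sxl), iCLIP was carried out with an Ssx antibody and with control IgG in male SL2 cells, an embryonic Drosophila line. The comparison comprised 2 Ssx IP and 2 control IgG IP libraries and was deposited as 1 table of statistics per transcript region. The tables list 2159 5' UTR intervals of 1345 genes, 1921 CDS intervals of 1432 genes, 8796 intronic intervals of 2946 genes and 4299 3' UTR intervals of 2667 genes. Coverage was low, with a median of 3 reads per interval over the 4 libraries together in 5' UTRs and CDS, 5 in 3' UTRs and 6 in introns. Positive log2 fold changes were read as higher in the Ssx IP, a direction that is likely but not written in the tables. Coordinates are those of dm6, and each value is that of 1 interval with the standard error given by the authors.

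The first question was which 3' UTRs were recovered with Ssx above the IgG background. In the authors' deposited table for 3' UTRs, 65 of 178 tested genes were enriched in the Ssx IP and 2 were depleted at an adjusted p under 0.05. The authors' adjustment covered further intervals, so these 178 may not be all the genes tested by them. The smallest adjusted p belonged to Cyp1, which encodes a cyclophilin-type peptidyl-prolyl isomerase. In the authors' deposited table its 3' UTR interval (X, 16317673 to 16318181, minus strand) had a log2 fold change of 5.28 ± 0.93 (SE, DESeq2 adjusted p = 6.5e-06) at a mean of 65.4 normalized reads. The highest mean among enriched genes, 97.3 normalized reads, was that of dm (X, 3385313 to 3391697, plus strand), the Myc transcription factor, with a log2 fold change of 3.03 ± 0.59 in the authors' deposited table (DESeq2 adjusted p = 3.83e-05). Its interval overlaps a non-coding gene, CR44999, on the same strand. CG44325 (4.81 ± 0.87) and Hsc70-3 (3.40 ± 0.72), which encodes the chaperone BiP of the endoplasmic reticulum, had the next highest means in the authors' deposited table, 71.7 and 74.6 normalized reads.

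The largest 3' UTR fold change in the authors' deposited table, 5.49 ± 1.40, was that of the ribosomal protein gene RpL17 (X, 6741537 to 6741776, minus strand). Further large values in the authors' deposited table were those of Galphaq, a G protein subunit (4.96 ± 1.46), CG11151 (4.96 ± 1.45), CG12643 (4.95 ± 1.45) and ade5, now named Paics, an enzyme of purine synthesis (4.74 ± 1.05). CG45086 overlaps Galphaq on the same strand and has the same value in the authors' deposited table, so the gene of origin of these 85 reads is uncertain. The enriched 3' UTR intervals spanned log2 fold changes of 2.01 to 5.49 in the authors' deposited table, with a median of 3.43. The depleted genes were Jabba, a lipid droplet protein, at -5.21 ± 1.35, and CG9947, now named Cdc50, at -2.78 ± 1.16 in the authors' deposited table. The call of CG9947 was close to the threshold (DESeq2 adjusted p = 0.0463) and was lost at 0.0519 when the adjustment covered only the intervals listed with an adjusted p.

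In 5' UTRs, 9 of 82 tested genes were enriched and 0 were depleted in the authors' deposited table, in which 46 intervals had an unadjusted p under 0.05 by DESeq2. The median log2 fold change was 3.26 over the tested 5' UTR intervals and 0.74 over all listed ones. At 2 to 9 reads, 88.4% of X-linked and 78.5% of autosomal 5' UTR intervals were also positive. The 5' UTR intervals were thus shifted up as a whole, and the values below are to be read against that shift. After scaling, the totals of the 4 unnamed libraries were still unequal, at 2403, 3759, 916 and 556. What the scaling adds to the shift, and so to the calls and shares in 5' UTRs, was not tested. RpS6 (X, 7901249 to 7901331, minus strand) had the largest value in the authors' deposited table, a log2 fold change of 6.47 ± 1.55 (DESeq2 adjusted p = 0.00568). Of the 9 genes, 4 encode ribosomal proteins, and the other ribosomal protein genes had values of 5.27 ± 1.63 for RpS19a, 4.82 ± 1.65 for RpL17 and 4.77 ± 1.66 for RpS5a in the authors' deposited table. The remaining genes in the authors' deposited table were B4 (5.33 ± 1.63), tara (4.94 ± 1.65), the circadian repressor cwo (4.73 ± 1.67), CG10970 (4.20 ± 1.47) and CG7231 (4.16 ± 1.16). CG10970 shares its interval in part with CG44325. Apart from RpS6, the adjusted p-values of these genes lay between 0.0206 and 0.049 in the authors' deposited table, and none of the 9 calls was kept with an adjustment over all listed intervals. Over the 4 regions together, 4 were kept and those of tara, RpL17, RpS5a, CG10970 and cwo were lost.

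Introns showed signal in both directions, with 24 of 507 tested genes enriched in the Ssx IP and 35 depleted in the authors' deposited table. By mean, the leading enriched introns in the authors' deposited table were those of v(2)k05816, the fatty acid synthase FASN2 (329.3 normalized reads, log2 fold change 2.62 ± 0.65), of the immunoglobulin-superfamily adhesion genes kirre (170.0, 2.22 ± 0.62) and hbs (154.7, 2.81 ± 0.63), and of CG42335 (137.5, 2.64 ± 0.65). The hbs interval (2R, 15011831 to 15035980, plus strand) had a DESeq2 adjusted p of 0.000903 in the authors' deposited table. The largest fold changes in the authors' deposited table were 4.46 ± 1.39 for RpL17, 4.14 ± 0.93 for CG44325, 4.11 ± 1.43 for CG32373, 4.06 ± 1.42 for Pka-R1, a regulatory subunit of protein kinase A, and 4.04 ± 1.43 for the transcription factor CrebA. CG42324 (3.88 ± 1.23), CG17691 (3.84 ± 1.24) and CG17018 (3.75 ± 1.25) followed in the authors' deposited table. The CG32373 interval overlaps CG12262 and PGRP-SD on the same strand. The most negative values in the authors' deposited table were -5.62 ± 1.26 for Jabba, -5.16 ± 1.47 for GABA-B-R3 and -5.08 ± 1.12 for kl-3, a Y-linked dynein heavy chain gene. The Jabba intron contains the 3' UTR interval named above, and both hold 36 reads, so they are 1 observation. The adjusted p of CrebA, 0.0496 in the authors' deposited table, rose to 0.0506 with an adjustment over only the intervals listed with an adjusted p. With an adjustment over the 4 regions together, the calls of CG32373, Pka-R1, CrebA, CG17691 and CG17018 were lost, at adjusted p-values of 0.05004 to 0.0891, as were those of RpL28 and CtBP named below and, in 3' UTRs, of RpS5a, Jafrac1, Rbp2, brat, CG9947, Sxl and beta-Spec.

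In coding sequence, 0 of 1432 tested genes were called by the authors' DESeq2 test, which allows a share of up to 0.257%, a limit on calls at this coverage and not on binding. The smallest p in the authors' deposited table was 0.151 (adjusted p = 0.855), and 0 intervals had an unadjusted p under 0.05. Of the 1921 CDS intervals, 88 held 10 or more reads over the 4 libraries.

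The next comparison asked in which part of the transcript the enriched genes lay. In the authors' deposited tables, the enriched share of tested genes was 36.5% in 3' UTRs (exact 95% interval 29.4 to 44.0), 10.98% in 5' UTRs (5.14 to 19.8) and 4.73% in introns (3.06 to 6.96). Among genes with a mean of at least 10 the shares were 44.6% (54 enriched genes), 46.2% (6) and 7.0% (21). With so few 5' UTR genes the order of the 2 UTRs at this coverage is not settled. If the direction of the fold change were the opposite one, the shares would be 1.12%, 0% and 6.90%, with introns first. The tested intervals of these regions differed in coverage, with medians of 72 reads in 3' UTRs, 23 in 5' UTRs and 67 in introns. Each region was also scaled with its own size factors, so folds and shares are not on 1 scale between regions. The median log2 fold change of tested intervals was 1.85 in 3' UTRs, 3.26 in 5' UTRs and 0.71 in introns. The same 495 reads of CG44325 gave 4.81 in 3' UTRs and 4.14 in introns. Over the 4 regions, 92 genes were enriched in at least 1 region and 36 were depleted, with 0 genes in both sets. RpL17 was enriched in 5' UTR, intron and 3' UTR, RpS5a in both UTRs, and Act5C, CG44325 and mgl in intron and 3' UTR, the last of them named after the values were seen. The overlaps were 1 gene between 5' UTRs and introns (0.556 expected), 2 between 5' and 3' UTRs (0.632 expected) and 4 between introns and 3' UTRs (2.3 expected), and none of the 3 passed Fisher's exact test (two-sided, adjusted p = 0.466, 0.263 and 0.310). With 2 enriched 5' UTR genes among the 19 tested in both UTRs, 2 shared genes was the largest overlap possible. The test of 5' and 3' UTRs therefore could not pass. The enriched intron of RpL17 overlaps its enriched 5' UTR interval, and the intron and 3' UTR intervals of CG44325 hold the same 495 reads, so CG44325 is 1 observation and the intervals of RpL17 can hold the same reads. Without these genes the overlaps were 0 genes between 5' UTRs and introns and 3 between introns and 3' UTRs (1.91 expected).

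**Figure D1:**
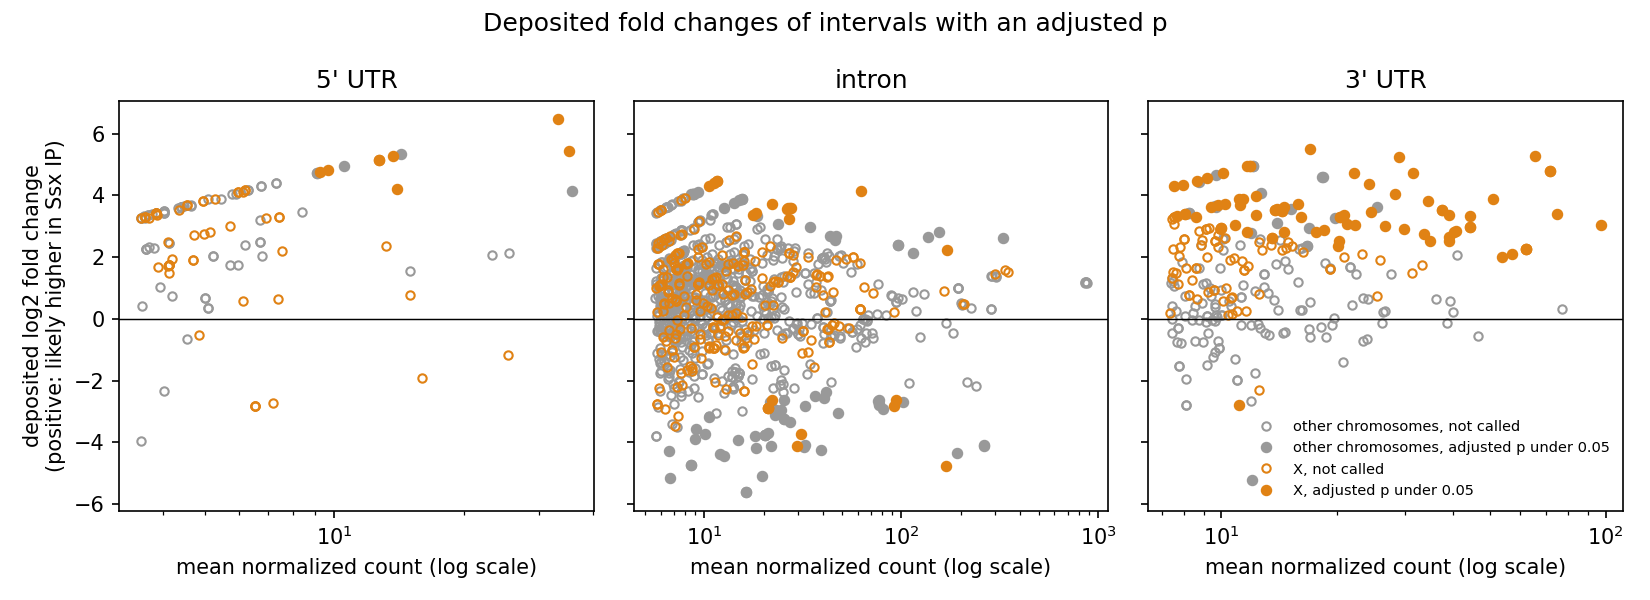
Deposited log2 fold change of each interval with an adjusted p (y axis, positive likely higher in the Ssx IP) against its mean normalized count (x axis, log scale) in 5' UTRs, introns and 3' UTRs, with X-linked intervals in orange and others in grey. Filled circles passed an adjusted p of 0.05: 13 intervals in 5' UTRs, 37 above and 57 below 0 in introns, and 96 above and 2 below 0 in 3' UTRs.

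Because Sxl acts in dosage compensation of the X chromosome, the chromosomal position of the enriched genes was examined. Among tested 3' UTR genes in the authors' deposited table, 52 of 86 X-linked genes (60.5%) and 13 of 92 autosomal genes (14.1%) were enriched. The odds ratio was 9.16 (95% interval 4.27 to 20.9, two-sided Fisher's exact test, p = 8.28e-11, adjusted p = 2.49e-10 over 3 regions). The X held 80% of the enriched 3' UTR genes, 48.3% of the tested ones and 23.7% of all listed ones. Between 7.41% (3R) and 20% (2R) of tested genes were enriched on the 4 large autosome arms. The median log2 fold change of X-linked genes in the authors' deposited table was 2.82 and that of autosomal genes 0.43, with 1 interval per gene. By the same exact test, 7 of 114 X-linked and 17 of 384 autosomal genes were enriched in introns (odds ratio 1.41, 0.482 to 3.70, p = 0.458, adjusted p = 0.478), and in 5' UTRs 5 of 34 and 4 of 48 (odds ratio 1.88, 0.371 to 10.3, p = 0.478, adjusted p = 0.478). The odds ratios of 3' UTRs and introns differed (Zelen's exact test, p = 0.00142, adjusted p = 0.00425), while those of 3' and 5' UTRs did not pass (p = 0.0572, adjusted p = 0.0858). These comparisons rest on the direction of the fold change. With the opposite one, chosen as an alternative after the values were seen, 1 of 86 X-linked and 1 of 92 autosomal genes would be enriched in 3' UTRs (odds ratio 1.07, 0.0135 to 84.9), 5 of 114 and 25 of 384 in introns (0.659, 0.192 to 1.81) and 0 in 5' UTRs, and 3' UTRs and introns would not differ by Zelen's exact test (p = 1).

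**Figure D2:**
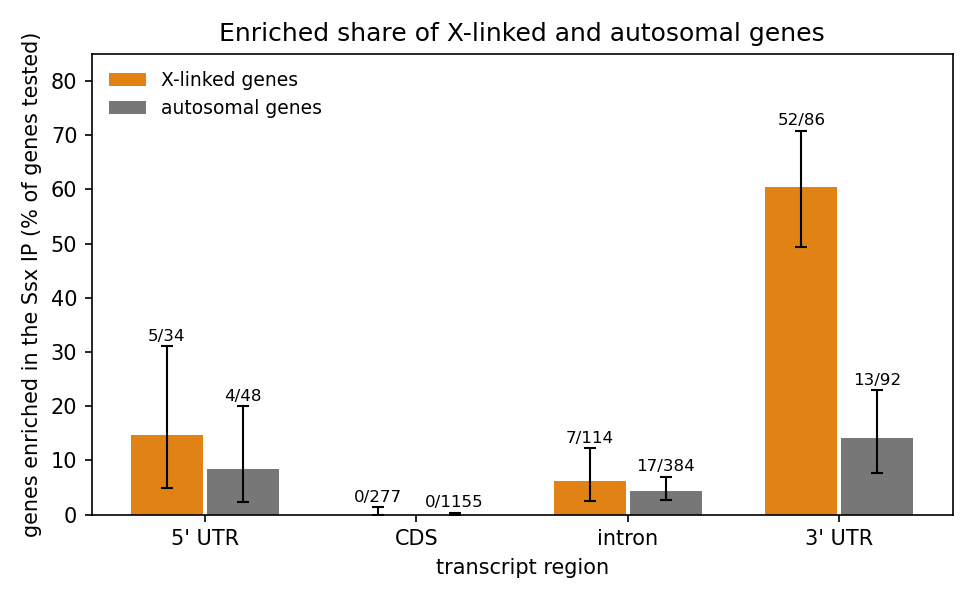
Share of tested genes enriched in the Ssx IP (y axis, percent) for X-linked and autosomal genes in each transcript region, with the number of enriched over tested genes above each bar and exact 95% binomial intervals as error bars. In 3' UTRs 60.5% of X-linked and 14.1% of autosomal genes were enriched, and in CDS none was.

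Genes of the sex determination and dosage compensation list were examined by name. The 3' UTR of Sxl (X, 7076710 to 7079302, minus strand) was enriched in the authors' deposited table, with a log2 fold change of 3.40 ± 1.40 (DESeq2 adjusted p = 0.0458) from 58 reads. This call lay close to the threshold, with adjusted p-values of 0.0513 to 0.690 under the other adjustments. The intron of Sxl with the smallest p had 2.38 ± 1.39 in the authors' deposited table (DESeq2 adjusted p = 0.268) and did not pass. The 3' UTR of ssx itself had 2.95 ± 1.29 in the authors' deposited table (DESeq2 adjusted p = 0.056), just above the threshold. The 3' UTR of msl-2, which encodes a subunit of the male dosage compensation complex, had 3.95 ± 1.56 in the authors' deposited table at an unadjusted p of 0.0111, and its 5' UTR had 3.21 ± 1.85 (p = 0.083), both listed without an adjusted p. The intron of msl-2 (0.99 ± 1.58) and that of ssx (-0.03 ± 1.59) were near 0 relative to their errors in the authors' deposited table and held 8 and 6 reads. The 5' UTR of Sxl (1.03 ± 1.94) and the CDS of ssx and Sxl (both 1.10 ± 1.41) and of msl-2 (-0.56 ± 1.36) did not pass in the authors' deposited table either. tra was not among the listed genes. Of the 3 members tested in 3' UTRs, 1 was enriched, and 0 were when the p-values were adjusted over the list alone.

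Among the other lists, ribosomal protein genes had the highest enriched share in 5' UTRs, 4 of 13 tested members (RpS6, RpS19a, RpL17 and RpS5a, 2 when adjusted over the list alone) against 7.25% of the other genes. This did not pass the adjustment over 18 list tests (two-sided Fisher's exact test, p = 0.0315, adjusted p = 0.568), and 0 of the 18 tests did. All 4 enriched genes are X-linked, out of 6 X-linked members tested. In introns 2 of 10 tested ribosomal protein genes were enriched, RpL17 and RpL28 (3.34 ± 1.12 in the authors' deposited table), and in 3' UTRs 2 of 4, RpL17 and RpS5a (3.62 ± 1.19), with 0 and 1 when adjusted over the list alone. Of 5 tested abundant housekeeping genes, 3 were enriched in 3' UTRs (3 when adjusted over the list alone), and in the authors' deposited table these were Hsc70-3, the actin gene Act5C (2.53 ± 0.77) and the peroxiredoxin gene Jafrac1 (4.48 ± 1.51). The Act5C intron was also enriched, at 3.73 ± 1.12 in the authors' deposited table. Of 7 tested cytoskeleton and adhesion genes, 3 were enriched in 3' UTRs (2 when adjusted over the list alone), and in the authors' deposited table these were the myosin light chain gene sqh (4.74 ± 1.22), Moe (2.51 ± 0.77) and beta-Spec (2.94 ± 1.24). Of 6 chromatin and transcription regulators tested in 3' UTRs, dm and the translational repressor brat (3.43 ± 1.40 in the authors' deposited table) were enriched (1 when adjusted over the list alone), and in introns 2 of 12 were, CrebA and the corepressor CtBP (3.06 ± 1.02), with 0 when adjusted over the list alone. In 3' UTRs the enriched members lay mostly on the X. Ribosomal protein genes had 2 of 3 X-linked and 0 of 1 other members enriched, and housekeeping genes 3 of 3 and 0 of 2. Cytoskeleton and adhesion genes had 3 of 5 and 0 of 2, and chromatin and transcription regulators 1 of 2 and 1 of 4. These list counts cannot be told apart from the X-linked excess.

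Single members of 4 further lists were enriched in the authors' deposited tables, the histone variant gene His3.3B in 3' UTRs (4.37 ± 1.09, 1 of 1 tested), Rbp2, now named eIF4H1, of the translation factors in 3' UTRs (3.06 ± 1.23, 1 of 2), the nuclear receptor gene Hr4 of the ecdysone list in introns (3.24 ± 0.97, 1 of 7) and Sxl of the long genes with many isoforms in 3' UTRs (1 of 6). When adjusted over the list alone, these counts were 1 for histones, 0 for translation factors, 2 for the ecdysone list and 0 for long genes. Adjusted in the same way, 1 gene was depleted in introns in each of the ecdysone, germline and non-coding RNA lists. None of the 10 splicing factors tested in introns and of the 5 tested in 3' UTRs was enriched. In introns, 0 of 24 non-coding RNA genes were enriched and 1, CR45082, named after its value was seen, was depleted. The Notch list had 0 enriched among 1, 2 and 1 members tested in 5' UTRs, introns and 3' UTRs. The list of Wnt and other signalling genes had 0 among 2, 10 and 1, and the list of RNA turnover genes 0 among 0, 0 and 1. Such small numbers say little about these lists. Markers of hemocytes, the lineage SL2 cells are thought to stem from, had 0 enriched among 2 tested in introns and 1 in 3' UTRs. Germline, neuronal and muscle markers had 0 enriched among 1, 2 and 1 tested in introns, and fat body markers and mitochondrially encoded genes had 0 tested members.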

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

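The Y-linked odds ratio and the tests on the size factors, on mature RNA and on the repeats were chosen after the patterns had been seen. The size-factor test of the Y-linked genes was first an odds ratio that only restated the pattern, then a difference of medians that also needed a 95% interval without 0, and last the permutation test used for the X, all with their values known. The odds ratio within quintiles of the mean value was planned before the data were examined, but was read against this explanation only after its value was seen. Those on the transcript part and on the reads in CDS were chosen before their results were seen.

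Intervals that the authors' deposited tables list without an adjusted p were not part of the comparisons. Among 4010 such 3' UTR intervals, 55 were higher in the Ssx IP at an unadjusted p under 0.05 and 2 were lower, and among 7773 such introns 31 were higher and 43 lower. What drew attention was the direction in 3' UTRs. The 55 intervals belong to 39 genes, of which 64.1% are X-linked, against 11.5% of the 26 genes of the 31 introns. Of the genes of the lower intervals, 0% of 1 in 3' UTRs and 23.5% of 34 in introns are X-linked, which would be the shares with the opposite direction of the fold change. The 55 higher 3' UTR intervals include that of msl-2, on 2L, with a log2 fold change of 3.95 in the authors' deposited table from 44 reads.

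The excess of X-linked genes among enriched 3' UTRs was weighed against technical explanations. Easier calling of well-covered intervals is argued against by the odds ratio within quintiles of the mean value, 12.7 (95% interval 5.42 to 29.7). Size factors shift X-linked and autosomal intervals alike and would give the 2 sets the same median. The medians differed by 2.39 (1.93 to 2.80, permutation test, p = 2e-05, the smallest that the permutations can give). With 52 of 86 X-linked genes called, this difference largely restates the excess and is no separate test of it. A higher amount of X-linked RNA in the Ssx IP in every part of the transcript would give the same difference between 3' UTR and intron folds on all chromosomes. In genes with at least 10 reads in both, that difference was higher by 1.21 in 112 X-linked than in 248 autosomal genes (0.859 to 1.56, permutation test, p = 2e-05), at a mean of 0.59 and -0.62. More mature X-linked RNA in the Ssx IP would likewise give the same difference between 3' and 5' UTR folds. That difference was higher by 1.53 in 45 X-linked than in 43 autosomal genes (0.815 to 2.24, permutation test, p = 0.0001), at a mean of -0.54 and -2.07. Mean folds in 3' and 5' UTRs were 2.10 and 2.64 in the X-linked genes, and 0.09 and 2.15 in the autosomal ones. Both expectations hold only for folds that are not moderated. Sparse folds are probably moderated here, so an equal X-linked excess could look smaller in 1 region than in another. Introns and 3' UTRs were therefore also compared at like reads, a choice made after seeing the data. At 30 to 99 reads the median folds of X-linked and autosomal intervals were 1.12 and 1.07 in introns, but 2.44 and 0.80 in 3' UTRs. Over tested genes the intron medians differed by 0.22 (-0.32 to 0.60). For these genes the values argue against an X-linked excess in introns as large as in 3' UTRs. A smaller one, and more mature X-linked RNA, are not decided against. Uncalled X-linked intervals with 2 to 9 reads were also more often positive in CDS (83.3% against 65.1%) and 5' UTRs (88.4% against 78.5%). Their median folds were nearly alike, 0.68 against 0.65 and 0.76 against 0.74. Both explanations, more X-linked RNA in every part and more mature X-linked RNA, thus stay open as a part of the signal. Binding of Ssx to 3' UTRs of X-linked genes may be considered as a hypothesis, if the direction of the fold change is as read here, but recovery of another protein with the antibody and a difference between the IP preparations stay open, because no other antibody and no cells without Ssx were included.

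Y-linked genes stood out among introns lower in the Ssx IP, with 5 of 8 tested Y-linked genes (Ccy, Ory, PRY, Ppr-Y and kl-3, all but kl-3 named after their values were seen) against 30 of 498 others. With the opposite direction of the fold change these 5 would be enriched and 0 lower. The odds ratio of 25.5 (4.71 to 172.1) describes a pattern that was seen first and is no test of it. A common shift through the size factors would give Y-linked and other genes the same median, and the medians differed by -2.49 (permutation test, p = 0.003). With 5 of 8 Y-linked genes called lower, this difference largely restates the pattern and is no separate test of it. With only 8 genes the 95% interval, -4.66 to 0.15, also reaches past 0, so no conclusion on the shift is drawn. Reads from repeated sequence, in which the Y is rich, could contribute to the signal of these 5 genes, and this cannot be told apart from a true difference without the genome sequence. No biological explanation was tested for this pattern.

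The lack of calls in CDS may come from low coverage. Only 4 CDS intervals held at least 58 reads, the median of the called 5' UTR intervals, and 5 held at least 45, the lowest number among them. At least 36 reads, the lowest number of a called 3' UTR interval, were held by 6, and at least 14, the lowest of a called intron, by 44. The Jabba 3' UTR with 36 reads and the GABA-B-R3 intron with 14 are depleted, so these 2 numbers are no measure for enriched calls. None of these CDS intervals was called, which does not decide whether coverage is the only reason.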

How the results depend on the processing

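Of the alternatives below, the adjustment over only the intervals with an adjusted p, 1 interval per gene, all listed genes as background, overlapping genes counted once and the overlap without overlapping intervals were chosen after seeing the data, as were the Y-linked odds ratio with all its alternatives and the turned direction. At an adjusted p under 0.01, 1 gene was enriched in 5' UTRs (1.22% of tested), 4 in introns (0.789%) and 32 in 3' UTRs (18.0%), 18 were depleted in introns and 1 in 3' UTRs, and the overlaps fell to 0, 0 and 1 gene. At 0.1, 61 genes were enriched in introns (12.03%) and the 3' UTR share was 44.4%, 4 genes were depleted in 3' UTRs, and introns and 3' UTRs shared 7. Without genes whose enriched intervals overlap, 5' UTRs and introns shared 0. Adjusted over the 4 regions together, 4 genes were enriched in 5' UTRs and 33 in 3' UTRs, with 1 depleted. Adjusted over all listed intervals, 0 were enriched in 5' UTRs (0%), 4 in introns (0.136%) and 16 in 3' UTRs (0.600%), and 12 were depleted in introns and 1 in 3' UTRs; more intervals tested is the construction behind these drops. Adjusted over only the intervals with an adjusted p, or with 1 interval per gene, 1 gene was depleted in 3' UTRs. With a minimum mean of 10, the enriched shares were 46.2%, 7.0% and 44.6% in 5' UTRs, introns and 3' UTRs, of fewer genes.

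The X odds ratio in 3' UTRs stayed between 7.87 and 13.95 under the 7 alternatives that keep the direction, and was 1.07 with the direction turned. In 5' UTRs it passed with all listed genes as background (4.35, Fisher's exact test, p = 0.0316), where genes with too few reads to be tested count as not enriched; in introns no alternative passed. The Y odds ratio lay between 17.2 and 348.3. Of the named genes' calls, 19 were lost with the adjustment over the 4 regions, 35 over all listed intervals and 5 over only the intervals with an adjusted p (Sxl, brat, beta-Spec, CG9947, CrebA), and 0 changed sign, since the fold changes are fixed.

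No paired analysis was possible because the tables have no columns per library. The 4 libraries solved from the means carry no names, and placing them in groups by their values was not done, so no library was left out and no other test, scaling or pseudocount was run. The uridine runs were not run, for want of a genome sequence used here.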

Other observations

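The test of transcript parts by coverage and the library values below were chosen after seeing the data. Among intervals that were not called, those of X-linked genes were more often positive in the authors' deposited table for 3' UTRs, with 69.6% of 362 X-linked and 50.8% of 1589 autosomal intervals at 2 to 9 reads, 86.5% of 148 and 53.1% of 390 at 10 to 29, and 97.8% of 92 and 73.2% of 112 at 30 to 99. At 100 or more reads they were 100% of 7 and 73.3% of 15. In CDS the shares were 83.3% of 324 and 65.1% of 1365 at 2 to 9 reads, 75% of 20 and 63.3% of 49 at 10 to 29, and 100% of 3 and 33.3% of 6 at 30 to 99. In 5' UTRs they were 88.4% of 301 and 78.5% of 1073, 95.5% of 66 and 90.4% of 83, and 80% of 10 and 100% of 11 in the same bands, so a higher X share is not particular to 3' UTRs. In introns the shares of positive intervals were 54.9% of 641 and 53.5% of 2475, 63.3% of 210 and 69.4% of 775, and 80.2% of 96 and 78.2% of 349, with 75.6% of 45 and 73.1% of 134 at 100 or more reads. The other regions had at most 2 intervals per set at 100 or more reads. Intervals of a gene are not independent, and no test was made on these shares.

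The whole reads solved from the mean values give 4 libraries per table that carry no names, so their values stand without groups. In 3' UTRs the X held 47.7%, 54.3%, 18.8% and 20.3% of reads, in the order of decreasing size factor (2.09, 1.66, 0.760 and 0.473), so the libraries fell into a higher and a lower pair. Exact 95% intervals, which cover counting error only, were 46.9 to 48.4, 53.5 to 55.0, 17.6 to 19.9 and 18.5 to 22.3. In introns the X shares were 20.5%, 20.5%, 17.8% and 21.4%, and the Y shares 1.05%, 0.965%, 2.71% and 2.40%. The X shares were 34.7%, 34.5%, 23.7% and 31.0% in 5' UTRs and 23.3%, 23.5%, 28.6% and 17.4% in CDS, each in the order of decreasing size factor. Without the 20 X-linked 3' UTR intervals with the most reads, the X shares were 37.6%, 42.7%, 15.8% and 17.1%.

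In the CDS table the size factors were not ordered like the reads. The library with the largest size factor, 1.67, held 2201 reads and that with 0.841 held 2983, while in introns 2.60 went with 70356 reads and 0.402 with 6038. The 10 CDS intervals with the most reads took 29.4% of the reads of the former library and 5.60% of those of the latter.

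Among enriched 3' UTRs, several genes also carry reads that 2 annotations share. CG44325 and CG10970 overlap on the X (9070684 to 9071583 and 9070066 to 9071408, minus strand) and account for enriched intervals in 3' UTRs, introns and 5' UTRs, where the same 495 reads appear in the 3' UTR and intron tables.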
